A study of Drosophila melanogaster with 2 samples.

How the data were processed

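Chromatin immunoprecipitation with sequencing was done on whole Drosophila melanogaster embryos aged 0 to 24 h that carried a GATAe-eGFP fusion, per the labels, with an antibody against GFP and chromatin sheared by sonication to 200 to 800 bp. There was 1 group of 2 samples, biological replicates 1 and 2 as the labels number them. A control experiment is named in the labels and was not used here. The aligner and the peak caller are not given in the sources used here, and the read depth of each replicate is unknown, so no value carries a depth and intervals cover counting error only.

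The authors deposited peak lists on the dm6 assembly. Each replicate had a ranked list and a thresholded list, and the series had 2 of each, 1 pairing the replicates and 1 from pooled reads, per the labels and the files' own record of what each was derived from. In each list the authors gave a score per peak, which was checked against the irreproducible discovery rate (IDR, the estimated share of peaks that would not be found again) in the ranked lists and stops at 830 in every thresholded list, an IDR of 0.01. The deposited signal value is the authors' measure of peak strength, and it is not on a common scale between lists. The deposited ranked lists also give −log10 of the IDR. The thresholded lists were derived with 1 more input than the ranked lists, per the deposited record, which does not say what that input is.

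The conservative list, which pairs the replicates, was the main list. Its 15 peaks off the chromosome arms were counted and not placed in genes, and none was mitochondrial. Coordinates are 1-based dm6 positions. Gene models came from Ensembl release 115 and sequence from the RefSeq copy of the same assembly. As a check that these match, 99.9% of 16237 annotated start codons read ATG in the sequence, and every peak ended inside its chromosome. Transposable elements and pseudogenes were left out of the annotation. Computation used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. The overlap count was checked with bedtools 2.31.1.

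Replicate overlap was the share of replicate 2 peaks with at least 1 bp in a replicate 1 peak, set against 1000 circular shifts along each chromosome (one-sided). Summits were put in 1 of 4 classes in the order within 500 bp of a TSS, exon, intron, intergenic, against 1000 sets of random positions on the same chromosomes (two-sided). Peaks per arm were tested with an exact binomial test against assembled length. WGATAR within 50 bp of a summit was compared with windows centred 500 bp to either side, exchanging summit and flank within each peak 100000 times (two-sided), and 6-mers were compared between the same windows with Fisher's exact test. Strength was related to the word by Spearman's rho with 100000 permutations. For gene lists, a gene was occupied if a summit lay in its body or up to 2 kb upstream, and the number occupied was set against 10000 random protein-coding lists matched on window length in 10 bins (two-sided). P-values were adjusted by Benjamini-Hochberg within each family. Peaks near each other are not independent, and the tests treat them as if they were, apart from the shifts.

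The 14 gene lists and the main tests were fixed before the data were examined. Symbols matched except LysC and Mex1, and 1 symbol matched under an older name. Genes named are those with the nearest protein-coding TSS to the 20 strongest main-list peaks, all 5 GATA factor genes, and up to 4 members of each list with the strongest peak in their window. The other members of the list of endoderm and midgut transcription factors were added after their values were seen. Other settings fixed before the data were examined were each replicate's own list, the other series-level list, other overlap rules, other window widths, other GATA words, another background, other ways to assign summits to genes, and random lists without matching. The stronger part of the list by signal, an IDR of 0.05, merged peaks beyond the count, 50 length bins, the lower replicate signal, peaks with a signal of 20 or more, the counting of sequences assigned to a chromosome but not placed on it, the list with nothing left out at an IDR of 0.01 and the tests of neighbouring genes, of promoter signal, of other GATA cores and of the WGATAR share in the region of srp, GATAe and pnr were chosen after the data were seen.

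The statistics were tested on simulated data. All 300 shared peaks placed among 1000 were found in the overlap step, all 600 words placed in 2000 windows were found in the motif step, and the 6-mer placed there ranked 1 among all 6-mers. Placed peaks had the same coordinates in both lists and placed words lay whole in windows of random bases. Finding them all therefore checks the counting alone. Of 200 random lists of long genes among 4000 simulated genes, 9 had a p under 0.05 in the gene list step. The simulated genes were occupied independently, while real neighbouring genes can share a summit. With 300 of 2000 random summits moved to TSSs, the location step gave a ratio of 2.04, against 1.08 with none moved.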

Results

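The series mapped where the GATA-family transcription factor GATAe binds in the Drosophila melanogaster embryo. GATAe is a zinc-finger protein of the endoderm and the midgut that recognises GATA sequences. Flies carried a fusion of GATAe with enhanced green fluorescent protein (eGFP), chromatin was taken from whole embryos aged 0 to 24 h, and the tagged protein was precipitated with an antibody against GFP. There was 1 group with 2 biological replicates, and no group was set against another. The data were peak lists on the dm6 assembly, so the number of reads behind each replicate is unknown. The main list was the conservative list that pairs both replicates, with 3047 peaks, of which 3032 lay on the chromosome arms. Some of the 3047 overlap, and merging them leaves 2779 places. The results count each peak unless merged peaks are named. Signal values are the authors' own, peak by peak, and serve here to rank peaks within a list.

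Most peaks of replicate 2 were also called in replicate 1. Replicate 1 had 2479 peaks past the authors' threshold and replicate 2 had 1822. Of the 1765 replicate 2 peaks on the arms, 1403 (79.5%, exact 95% interval 77.5 to 81.4%) shared at least 1 bp with a replicate 1 peak. In the other direction, 1356 of 2476 replicate 1 peaks (54.8%) met a replicate 2 peak. Shifting the replicate 2 list along each chromosome 1000 times gave a mean of 20.1 shared peaks and at most 37, so the one-sided permutation p was 0.001, the smallest that number of shifts can give. Across the shared peaks, which are not independent replicates, Spearman's rho of the 2 signal values was 0.650 and Pearson's r of their log2 values was 0.50. The second series-level list, made from pooled reads, held 2947 peaks, and 2470 peaks stood in both series-level lists. Of the 3032 main-list peaks on the arms, 1411 overlapped thresholded peaks of both replicates and 596 overlapped none of either.

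The strongest peak of the main list lay in GATAe itself. It covered positions 16011948 to 16012313 of arm 3R, in an intron of GATAe (FBgn0038391), with its summit 153 bp from an internal annotated transcription start site (TSS) of the gene. Its signal value was 958 in the main list, 449 in replicate 1's own ranked list and 501 in replicate 2's. It was the highest value of replicate 2 but not of replicate 1. There the peaks named below for Ugalt (523), CG11050 (509) and CG14100 (454) were higher. A summit lay in the window of all 5 GATA factor genes, where a window is the gene body plus 2 kb upstream. Random lists of 5 genes with matched window lengths held 1.77 such genes on average (two-sided permutation p over genes of like window length = 0.0116, Benjamini-Hochberg adjusted p = 0.0406 over 14 lists). The random lists treat genes as independent, although 3 of the 5 lie in 1 region. The adjusted permutation p was 0.106 in replicate 2's own list, 0.0429 in replicate 1's, 0.129 at an IDR (irreproducible discovery rate) of 0.05 and 0.116 in the stronger part of the list by signal.

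GATAe sits between 2 other GATA genes, srp (serpent, which acts in endoderm, haemocytes and fat body) and pnr (pannier, which acts in dorsal ectoderm and heart). The 59.6 kb from 15984152 to 16043796 on 3R that hold all 3 genes carried 11 main-list peaks, and 9 of their summits had the GATA word WGATAR (W is A or T, R is A or G) within 50 bp. The strongest peak at pnr (FBgn0003117) covered 16025834 to 16026052, upstream of the gene in intergenic sequence and 158 bp from its TSS, with a signal of 498. The strongest at srp (FBgn0003507) covered 15985713 to 15986081, also intergenic, 277 bp from the TSS, with a signal of 426. The remaining GATA genes had 1 summit each. The GATAd (FBgn0032223) peak was intronic, at 10334906 to 10335056 on 2L, with a signal of 222. The grn (grain, FBgn0001138) peak was intronic too, at 8180344 to 8180703 on 3R, with a signal of 63.1, rank 2611 in the main list.

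**Figure D1:**
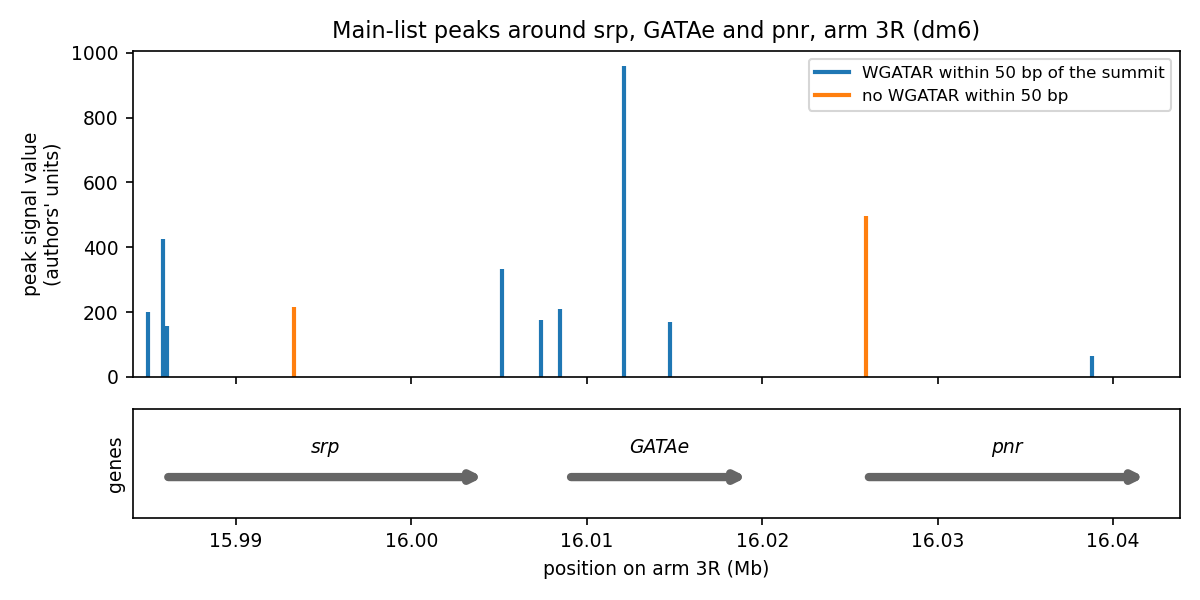
Main-list peaks in the region of srp, GATAe and pnr. Each vertical line is 1 peak at its summit position on arm 3R (horizontal axis, Mb, dm6), its height is the authors' signal value, its colour shows whether WGATAR lies within 50 bp, and arrows show the genes in their direction of transcription; the tallest line, 958, is inside GATAe.

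The other strongest peaks lay mostly near transcription start sites. Of the 20 peaks with the highest signal, 14 had a summit within 500 bp of an annotated TSS, 4 were in introns, 1 was in an exon and 1 was intergenic. The second strongest, at 2703727 to 2704028 on X, was intergenic and 30 bp from the TSS of Ugalt, a UDP-galactose transporter gene, with a signal of 922. The next were an intronic peak in CG11050 at 6612563 to 6612864 on 2L, with a signal of 875, an intergenic peak 94 bp from the TSS of CG14100 at 19590485 to 19590748 on 3L, with 761, and an intergenic peak 135 bp from the TSS of mRpL41, a mitochondrial ribosomal protein gene, at 15217610 to 15217885 on 2R, with 724. Peaks with signal values from 503 to 659 had as their nearest protein-coding TSS that of AhcyL2, Tcs5, CG5096, ph-p (a Polycomb group gene), Svil, Art3, Sox14, Rab32, CG7601, p130CAS, CG18480, HmgZ, Ppa, SmD3 or Trl (the gene of GAGA factor). WGATAR lay within 50 bp of 9 of the 20 summits, and a bare GATA within 50 bp of 15. Over all main-list summits on the arms the shares were 46.0% and 72.1%, so the 20 strongest were close to the whole list. A bare GATA is common, and its share at all summits was 1.50 times that of flanks.

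In the main list, 2 lists carried peaks more often than genes of like window length. They were the transcription factors of endoderm and midgut, called midgut regulators below, and the genes of midgut epithelium and junctions. The random lists matched window length alone, so promoter activity was not allowed for. Cytosolic ribosomal protein genes had a ratio of 2.72 in the same test, so the excess was not particular to midgut lists. Of 19 transcription factors of endoderm and midgut, 12 were occupied against 5.79 in random lists, 2.07 times as many (adjusted permutation p = 0.0233). The highest signal in this list was at Ptx1, a homeobox gene, in an intron at 30915365 to 30915557 on 3R, with 317. Then came hth with 187 and drm with 162, and nub, a POU-domain gene, with 155. The hth summit lay 93616 bp from a TSS of hth, in a window of 134 kb. Of the rest, bowl (154), cad (143), lab (120), Hnf4 (118) and the forkhead gene fkh (115) had summits. So did lin (70.4), dve (68.1) and Sox100B (67.6). The other members, hkb, tll, byn, esg, tsh, exd and Sox21a, had none. The adjusted permutation p of this list rose to 0.0784 in replicate 2's own list, 0.128 in replicate 1's, 0.140 at an IDR of 0.05 (ratio 1.59) and 0.0756 in the stronger part of the list by signal.

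Of 18 genes of midgut epithelium and junctions, 12 were occupied against 5.69 in random lists, 2.11 times as many (adjusted permutation p = 0.0233). Tsp2A, Ssk and mesh, whose proteins belong to the smooth septate junction, the occluding junction of the midgut, had the highest signals of this list. The Tsp2A peak at 1346359 to 1346591 on X, in an intron of MTPAP and 72 bp from the Tsp2A TSS, had a signal of 391 and 3 WGATAR words. The Ssk peak at 20188195 to 20188538 on 3L, in an intron of CG42674 and 118 bp from the Ssk TSS, had 376 and 2 words. The mesh peak at 31195651 to 31195927 on 3R was intergenic, 24 bp from the TSS, with 299 and no word. The list also holds general epithelial genes, such as the cell polarity gene scrib, which had 7 summits, the strongest with 286. With summits counted only within 1 kb of a TSS, the adjusted permutation p was 0.0504 for this list, 0.267 for the midgut regulators and 0.0756 for the GATA factors. In the stronger part of the list by signal it was 0.148 for the junction genes.

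Digestive enzyme genes of the midgut did not pass the test. Of 51, 10 were occupied against 5.58 in random lists (adjusted permutation p = 0.198), with signal values of 104 at the serine protease gene Ser6, 81.9 at thetaTry and 81.9 at a peak shared by Jon65Aiii and Jon65Aii. The ratio to random lists, 1.79 in the main list, turned to 0.299 in replicate 2's own list, 0.971 in replicate 1's and 0.307 in the stronger part of the main list by signal. Among 20 subunits of the vacuolar ATPase, the proton pump, 3 were occupied against 3.89 (adjusted permutation p = 1), namely Vha16-1 with 199, Vha100-2 with 121 and Vha68-1 with 89.7.

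The lists for other tissues did not pass the test either. Each signal value below is that of the strongest peak in the gene's window, which can lie in another gene or far from a TSS. The elav and Mef2 peaks, for example, lay in introns of arg and Pal1, 261 and 1072 bp from a TSS of the named gene. The pros summit lay 18652 bp from a TSS of pros. Malpighian tubule genes had 8 of 22 occupied against 6.65, with fray at 160, ct at 123, Irk1 at 104 and SecCl at 94.6. Haemocyte genes had 5 of 21 against 6.14, with zfh1 at 217, Pvr at 129, ush at 111 and PPO1 at 83.0. Fat body genes had 7 of 19 against 4.72, with Lpin at 314, FASN1 at 120, bmm at 91.5 and Lsd-2 at 89.7. Genes of dorsal ectoderm, amnioserosa and heart had 4 of 16 against 4.42, namely ths at 152, Doc3 at 151, tin at 134 and pyr at 72.9. Nervous system genes had 5 of 25 against 7.78, with elav at 243, pros at 158, nSyb at 118 and ChAT at 82.3. Muscle genes had 8 of 24 against 7.40, with Mef2 at 301, Msp300 at 209, kirre at 151 and rols at 124. Adjusted permutation p-values of these 6 lists ran from 0.581 to 1. The direction turned with 1 replicate alone for fat body (ratio 1.48 in the main list, 0.944 in replicate 2's own list), Malpighian tubule (1.20, and 0.807 in replicate 1's) and dorsal ectoderm, amnioserosa and heart (0.906, and 1.01 in replicate 2's). Only rib, at 79.1, was occupied among 17 genes of epidermis, cuticle and trachea, against 4.88 in random lists (permutation p = 0.0488, adjusted permutation p = 0.137).

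Ribosomal protein genes had the lowest p of the 14 lists. Of 94 genes of cytosolic ribosomal proteins, 32 were occupied against 11.8 in random lists, 2.72 times as many (permutation p = 0.0002, the smallest 10000 random lists can give, adjusted permutation p = 0.0028). RpL34b at 259, RpS23 at 232, RpS27 at 178 and RpL7 at 148 had the highest signal values. Heat shock and chaperone genes had 4 of 19 occupied against 3.23 (adjusted permutation p = 1), namely Hsp27 at 216, Hsc70-5 at 99.5, Hsp83 at 86.1 and Hsp26 at 73.4, and their ratio of 1.24 became 0.996 in replicate 2's own list. Over the genome, 2657 of 13968 protein-coding genes had a summit in their window, and 230 summits lay in no such window.

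**Figure D2:**
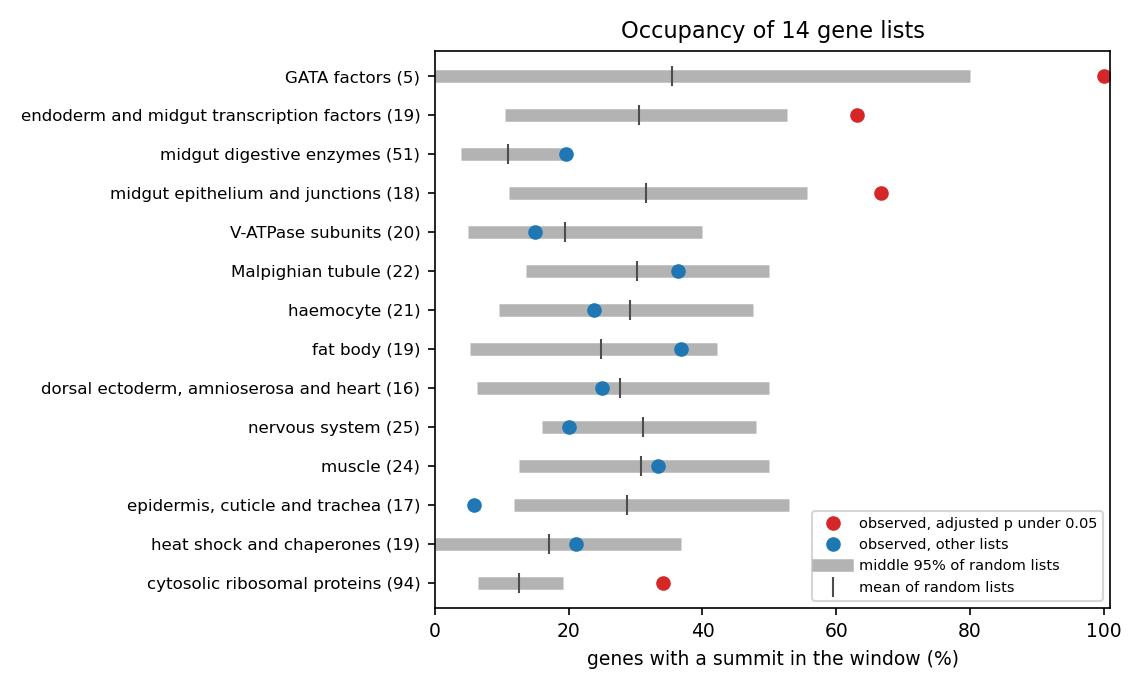
Share of genes with a main-list summit in the gene body or 2 kb upstream (horizontal axis, %) for 14 lists, with the number of genes in brackets. Points are observed shares, grey bars hold the middle 95% of 10000 random lists with matched window lengths and ticks their mean; 4 lists, in red, had an adjusted p under 0.05.

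Summits gathered at transcription starts. Within 500 bp of a TSS lay 1491 of the 3032 summits (49.2%, exact 95% interval 47.4 to 51.0%), against 13.5% of random positions, a ratio of 3.64. Exons outside these stretches held 3.46% of summits against 19.6% of random positions, and intergenic sequence held 9.23% against 27.6%. All 3 differences had an adjusted two-sided permutation p of 0.00133 over 4 classes. Introns held 38.1% against 39.2% (adjusted permutation p = 0.212), but the difference was past the threshold in each replicate's own list, with ratios of 0.901 and 0.939. The median summit was 612 bp from the nearest protein-coding TSS.

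**Figure D3:**
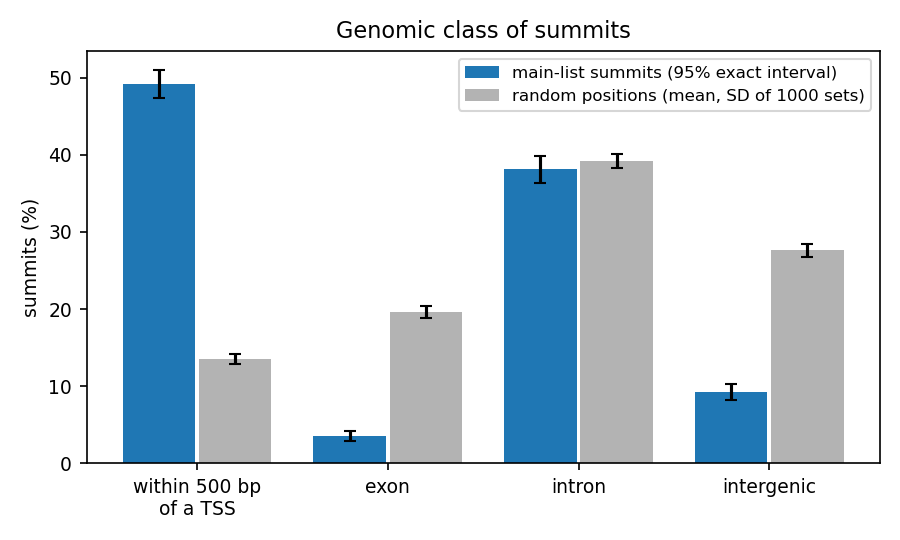
Share of summits (vertical axis, %) in 4 genomic classes for 3032 main-list summits (blue, exact 95% intervals) and for 1000 sets of random positions on the same chromosomes (grey, mean with SD). The share within 500 bp of a TSS was 49.2% against 13.5%.

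Arm 2R carried somewhat more peaks than its share of the assembled length would give, and chromosome 4 and Y almost none. Arm 2R had 629 peaks, 24.9 per Mb and 1.13 times its share of the assembled length. Its adjusted p was 0.0022 in an exact binomial test, over 7 chromosomes or arms. Arm 2L had 564 peaks, 1.09 times its share, near the threshold (exact binomial test, adjusted p = 0.0395). It was not past the threshold in the stronger part of the list by signal (exact binomial test, adjusted p = 0.190). The total length includes 4 and Y, so their low counts raise the ratios of all other arms. A comparison among the other arms alone was not run. Chromosome 4 had 3 peaks against 29.7 from its length (exact binomial test, adjusted p = 3.34e-09), and Y had 0 against 80.8 (adjusted p = 3e-35). Expected counts rest on assembled length alone. They allow neither for stretches where reads cannot be placed nor for the number of copies of X and Y. The low counts on 4, Y and X therefore do not by themselves show less binding. In the exact binomial tests, the values for 3L (668 peaks, ratio 1.08, adjusted p = 0.0395) and X (475 peaks, ratio 0.915, adjusted p = 0.0395) were near the threshold, and 3R was not past it (693 peaks, ratio 0.980, adjusted p = 0.562). Neighbouring peaks are not independent, which makes these p-values too small, and the calls for X and 3L were lost in replicate 1's own list (exact binomial test, adjusted p = 0.235 for both). In replicate 2's own list the call for 3L was lost too (exact binomial test, adjusted p = 0.402) and that for X held (adjusted p = 0.0191).

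The sequence that GATA factors recognise marked the summits. WGATAR lay within 50 bp of 1396 of 3032 summits (46.0%, exact 95% interval 44.3 to 47.8%) and in 20.6% of windows of the same width 450 to 550 bp away on either side of the same peaks, a ratio of 2.23 (two-sided permutation p = 1e-05, the smallest 100000 resamples can give). The excess was present in every genomic class. The share was 41.6% against 19.3% in flanks near a TSS, 52.4% against 22.4% in introns, 56.2% against 21.4% in exons and 39.3% against 20.2% in intergenic sequence, each with permutation p = 1e-05. In windows of 21 bp the share was 10.9% at the summit itself.

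**Figure D4:**
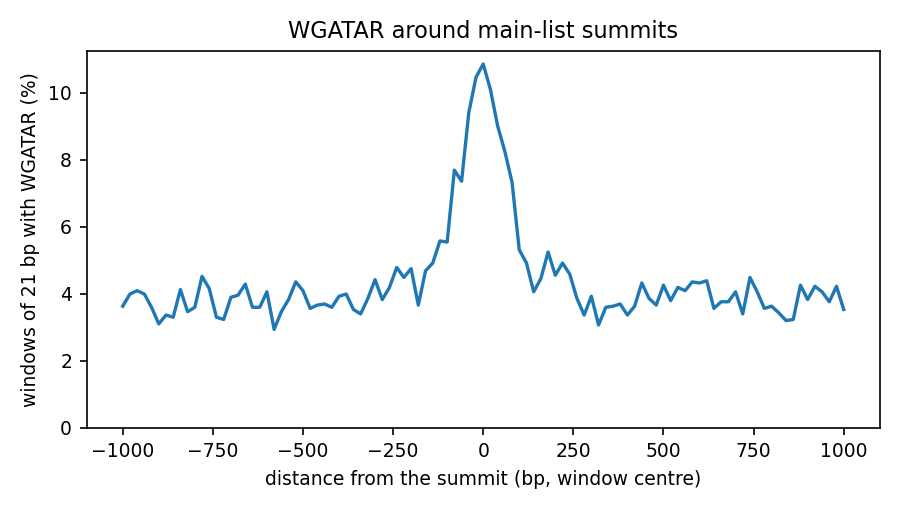
Share of 21 bp windows that hold WGATAR (vertical axis, %) by distance of the window centre from the summit (horizontal axis, bp) over 3032 main-list summits, in steps of 20 bp out to 1000 bp. The share peaks at 10.9% at the summit.

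Among all possible 6-mers, with both strands counted together, the one with the lowest p was GATAAG, counted as its reverse complement CTTATC. It lay within 50 bp of 28.9% of summits and in 7.04% of flank windows, a ratio of 4.10 (Fisher's exact test, adjusted p = 6.91e-159). TGATAA (23.9% against 8.87%), CTGATA (16.3% against 4.83%), ATAAGA (18.4% against 6.20%) and CGATAA (15.7% against 4.98%) followed, then AGATAA, ATCTTA, GCGATA, GATAAC and ATAAGC. Of these 10 words 7 contain GATA on one strand. Of the 48 words of this length that contain GATA, 36 were more frequent at summits and 5 less frequent, at an adjusted p under 0.05. In all, 202 words were more frequent and 288 less frequent.

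The share of summits with WGATAR did not rise steadily with strength. In 5 equal groups from weakest to strongest it was 39.9% (exact 95% interval 35.9 to 43.9%), 43.4%, 47.5%, 52.5% (48.4 to 56.5%) and 47.0% (42.9 to 51.0%), while flanks stayed between 19.5 and 22.9%. The weakest group held 196 peaks with a signal under 20, of which 193 overlapped another main-list peak and 27.0% had the word, and its other 411 peaks had it at 46.0% (41.1 to 50.9%), the share of the whole list. Spearman's rho between signal and presence of the word, across peaks, was 0.0724 (two-sided permutation p = 0.00011, adjusted p = 0.00011 over 2 relations). The share of summits near a TSS went from 43.7% in the weakest group to 56.0% in the strongest (rho = 0.0952, permutation p = 1e-05, adjusted p = 2e-05). The relation of the word to strength was not past the threshold in replicate 1's own list (rho = 0.0283, permutation p = 0.16) with overlapping peaks merged (rho = 0.0294, permutation p = 0.126) or among peaks with a signal of 20 or more (rho = 0.0339, permutation p = 0.0708), and turned to -0.0357 in the stronger part of the list (permutation p = 0.164). It was 0.0627 in replicate 2's own list (permutation p = 0.0085), 0.0637 with the lower signal of the 2 matched replicate peaks (permutation p = 0.0005), 0.129 at an IDR of 0.05 and 0.0886 in the pooled list, all past the threshold by permutation.

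**Figure D5:**
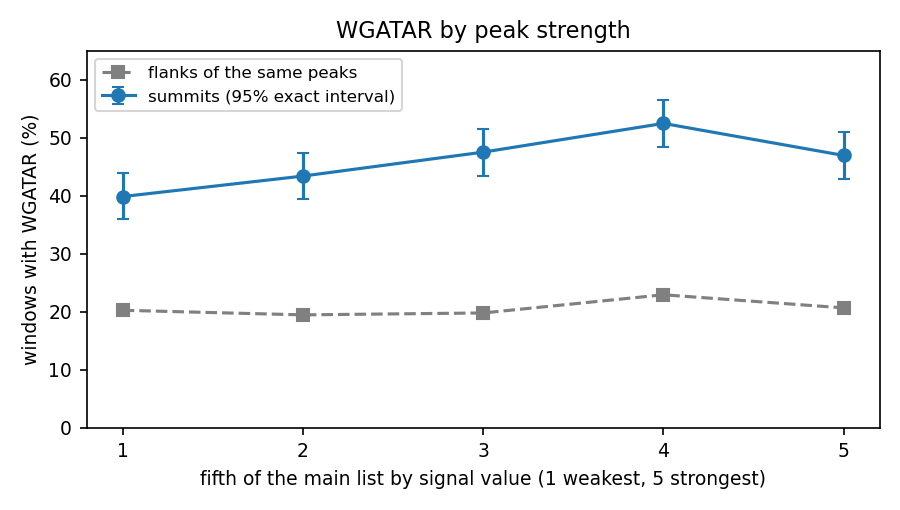
Share of windows with WGATAR (vertical axis, %) at summits (blue, exact 95% intervals) and in flanks of the same peaks (grey) for 5 equal groups of main-list peaks ordered by signal value (horizontal axis). The highest share, 52.5%, was in the group next to the strongest.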

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

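The tests of neighbouring genes, of promoter signal, of other GATA cores and of the WGATAR share in the region of srp, GATAe and pnr were chosen only after the results they bear on were seen.

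Data that the comparisons do not use held 2 signals. The ranked list that pairs the replicates had 102 peaks at an IDR of 0.01 or less that the conservative list left out, 89 of them on the arms, with 51 on 3R and 22 on 2L. The strongest, at 480945 to 481232 on 2L in an intron of ush with the TSS of cbt nearest, had a signal of 858, and Lk6, Unc-115a, larp, tara and trx had others of 247 or more in their introns, while 2 of 329 and 287 on X were intergenic, 111128 and 116363 bp from the nearest TSS, that of ATbp. WGATAR lay within 50 bp of 30 of the 89 summits (33.7%, exact 95% interval 24.0 to 44.5%), against 16.3% of flanks (permutation p = 0.00156). Many of these summits shared a nearest gene, with 6 at tara and 5 each at ATbp, Kdm2 and Rh5. They are not independent, so the interval is too narrow and the p too small. The main list also held 15 peaks on 13 sequences assigned to X but not placed on it, with signal values up to 305, which were not assigned to genes.

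Ribosomal protein genes were occupied 2.72 times as often as genes of like length. Counting each summit only for the gene with the nearest TSS left 23 of 94 genes against 7.50 in random lists, a ratio of 3.07 (adjusted permutation p = 0.0028), which argues against summits of neighbouring genes as the whole source. Signal at active promoters that does not depend on GATA sequence is a candidate explanation that stays open. Of the 40 summits in these windows, 34 of them near a TSS, 10 had WGATAR within 50 bp. That was 25.0% (exact 95% interval 12.7 to 41.2%), against 12.5% of flanks (permutation p = 0.119). All summits near a TSS had the word at 41.6% and the whole list at 46.0%. The excess over flanks was 12.5 points (95% bootstrap interval -2.5 to 28.8). This reaches from no excess to that of the TSS class, 22.3 points, and of summits away from TSSs, 28.4 points. With 1 group and no expression data used here, no biological explanation was tested.

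Of the 3032 summits, 1636 (54.0%) had no WGATAR within 50 bp. Promoter signal without GATA sequence stays open for these: 53.2% of them were near a TSS against 44.5% of the summits with the word, and the WGATAR excess of the TSS class over its flanks, 22.3 points (95% bootstrap interval 19.6 to 25.1), comes from the summits with the word and says nothing of those without. Inexact summits may account for part: 50 to 150 bp from these summits WGATAR was more frequent than in like windows around the flanks by 16.2 points (13.3 to 19.04), a value that clusters of sites would also give. GATA cores outside the WGATAR pattern may account for another part, since a GATA was more frequent at these summits than in flanks that also lack WGATAR by 14.9 points (11.8 to 17.9). At 847 summits, 27.9% of the list, no GATA at all lay within 50 bp, and no biological explanation was tested.

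The region of srp, GATAe and pnr had 11 main-list peaks, against at most 10 in the 535 other stretches of its length on 3R, and with overlapping peaks merged it had 10 places against at most 9. Extra copies of the locus from the tagged insertion, as the source of the separate peaks or of their height, cannot be told apart from stronger binding. WGATAR lay at 81.8% of its summits (exact 95% interval 48.2 to 97.7%) against 20.6% of flanks over the whole list, a value that would be seen with or without copies, since copies would also lift weak GATA sites past the threshold. The region held 36 weak candidate peaks with an IDR above 0.05 against a median of 29, the 74.4 percentile of the stretches, between the bounds set beforehand. The extent of the insertion is not given in the sources used here, 3 of the 5 GATA factor genes lie here, and binding of GATAe to its own locus and its neighbours remains a hypothesis.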

How the results depend on the processing

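The stronger 0.5 of the list by signal, the IDR 0.05 list, merged peaks beyond the count, 50 length bins, the list with nothing left out at an IDR of 0.01, peaks with a signal of 20 or more, the counting of sequences not placed on their chromosome and the lower replicate signal were chosen after seeing the data. The planned stricter IDR of 0.01 removed nothing, since every thresholded list already stops there. Of 262 values under alternatives, 205 kept their direction and side of the threshold or moved little. The TSS ratio stayed between 2.61 and 3.95 and the ribosomal protein ratio between 1.79 and 3.07. The WGATAR ratio stayed between 1.82 and 2.75. With other words it was 2.49 for AGATAA or TGATAA and 1.50 for a bare GATA. All of these were past the threshold. In each replicate's own list, peak counts were 1822 to 2479, the X ratio 0.871 to 0.946, the 3L ratio 1.05 in both (no longer past the threshold in either), the intron ratio 0.901 to 0.939, rho of WGATAR with strength 0.0283 to 0.0627, the GATA factor ratio 3.02 to 3.14, the midgut regulator ratio 1.87 to 2.24, and lists past the threshold 2 to 3 of 14. In the stronger 0.5 by signal, rho turned to -0.0357 (p = 0.164), the intron ratio of 0.888 passed the threshold, and the X (0.925), 2L (1.09), 3L (1.07), GATA factor (3.33), midgut regulator (2.34) and midgut junction (2.12) ratios no longer did, with 1 list left, and fewer peaks were tested. At an IDR of 0.05, with 4769 peaks, 3L (1.04), GATA factors (2.22) and midgut regulators (1.59) were lost and 2 lists remained past it. In the pooled list, X (0.948) and 3L (1.04) were lost. With summits within 1 kb of a TSS, GATA factors (3.86), midgut regulators (1.91) and midgut junctions (2.62) were lost and 1 list remained. With merged peaks rho was 0.0294, and among peaks with a signal of 20 or more 0.0339. Results not past the threshold in the main list also turned direction. In each replicate's own list the ratio was 0.299 to 0.971 for digestive enzymes (main 1.79), 0.944 to 1.39 for fat body (1.48), 0.807 to 1.08 for Malpighian tubule (1.20), 0.996 to 1.35 for heat shock (1.24) and 0.993 to 1.01 for dorsal ectoderm and heart (0.906). At an IDR of 0.05 it was 0.932 for Malpighian tubule, 1.03 for dorsal ectoderm and 1.04 for 3R (0.980), in the pooled list 0.799 for Malpighian tubule, and in the stronger part by signal 0.307 for digestive enzymes, 0.664 for fat body and 1.05 for dorsal ectoderm. With the nearest TSS alone it was 1.08 for V-ATPase (0.771), 1.25 for dorsal ectoderm and 1.14 for haemocyte (0.815), within 1 kb of a TSS 1.01 for V-ATPase, 1.04 for dorsal ectoderm and 0.875 for muscle (1.08), and without matching 1.32 for dorsal ectoderm, 1.25 for haemocyte and 1.05 for the nervous system (0.643). With 1000 bp around a TSS the intron ratio was 0.817, past the threshold. With summits within 100 bp, the correlation of replicate signals was 0.735. The cause of these changes was not tested. Read depth is unknown, so what it limits could not be set.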

Other observations

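The gene lists and words below were chosen after the data were seen.

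The bases next to GATA differed between summits and flanks. With GATAA fixed, a following G gave the ratio of 4.10 for summits against flanks, C gave 2.88, A gave 1.55 and T gave 1.44. With AGATA fixed, a following A gave 2.59, G gave 2.07, T gave 1.58 and C gave 1.32. Before GATAA, C (3.15), T (2.69) and A (2.59) were all more frequent at summits, while GGATAA was less frequent (0.646, Fisher's exact test, adjusted p = 0.0138). Some words with GGA and no GATA, such as CCAGGA (0.184) and GCAGGA (0.392), had lower ratios still. The value of GGATAA can therefore not be read as an effect of the base next to GATA. CGATAA lies outside WGATAR. At least 2 WGATAR words lay within 50 bp of 14.7% of summits against 3.23% of flanks, a ratio of 4.56, and exactly 1 word in 31.3% against 17.4%, a ratio of 1.80. The word TATCGATA, the binding site of the promoter factor DREF, lay at 40 summits, 1.32% against 0.198% of flanks (Fisher's exact test, unadjusted p = 1.35e-10). It contains GATA on both strands, and summits gathered at TSSs. The excess can therefore not be told apart from GATA content or promoter position, and binding of DREF was not tested. Among less frequent words CCAGGA stood lowest by p, in 0.66% of summits and 3.58% of flanks.

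Of 8 further gene lists, mitochondrial ribosomal proteins alone were past the threshold, with 16 of 73 genes occupied against 7.38 in length-matched random lists (adjusted permutation p = 0.0336). With each summit counted only for the gene with the nearest TSS, this excess was gone, with 5 of 73 against 4.63 (adjusted permutation p = 0.990). The strongest peaks were at mRpL41 (724) and in the window of mRpS10 (596), the latter being the peak named above for Art3. Polycomb and trithorax group genes had 11 of 20 against 5.70 (adjusted permutation p = 0.0832), with ph-p at 606, Trl at 503, brm at 454 and phol at 330. With the nearest TSS alone they had 7 against 4.21 (adjusted permutation p = 0.832). Genes of the EGF receptor pathway had 8 of 13 against 4.24 (adjusted permutation p = 0.156, and 0.0448 with the nearest TSS alone, 8 against 3.06), with 6 summits at pnt and 4 at aop. Ecdysone response genes had 8 of 13 against 5.02 (adjusted permutation p = 0.321), and 3 against 3.57 with the nearest TSS alone (adjusted permutation p = 0.990). The EGF receptor list was the only 1 of the 8 past the threshold with the nearest TSS alone. Notch, Wnt, JAK/STAT and Hippo pathway genes had 4 of 14, 5 of 16, 3 of 10 and 3 of 12 (adjusted permutation p = 1). The gene with the most summits was Eip75B, an ecdysone-induced nuclear receptor, with 12 in a window of 116 kb, followed by bun with 10 and sbb and shn with 9 each.

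Of the main-list peaks on the arms, 196 had a signal under 20, and 193 of these overlapped another main-list peak. WGATAR lay at 27.0% of their summits (exact 95% interval 20.96 to 33.8%) against 21.2% of flanks (permutation p = 0.119).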
